A study of Mus musculus with 18 samples.

How the data were processed

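Hippocampal RNA from 18 adolescent male C57BL/6J mice, 6 per group, was used as 1 library per mouse. Per the labels' protocols, tissue was snap-frozen, RNA with an integrity number of at least 7 was enriched for poly(A) RNA, and stranded libraries were sequenced on a NovaSeq X Plus instrument. All samples carry the same batch label. The authors deposited 1 table of estimated counts per gene and library, which are expected counts that need not be whole, with no normalization applied. Reads were trimmed with fastp, aligned with HISAT2 and counted with RSEM against GRCm38 (mm10), as far as the names in the submitters' processing notes tell; their versions, the order of the steps, the annotation release and the strand setting of the counting are not given in the sources used here. In the table, 22.7% of the nonzero values were not whole, and all were rounded to whole numbers before testing. RSEM divides reads that fit several genes, so the counts of gene families, predicted genes and pseudogenes with near-identical copies are uncertain, and overlapping or antisense genes are uncertain too.

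The table held 57180 gene identifiers, of which 51884 matched a symbol in the gene name table and 5296, with 0.62% of all counts, did not. The identifiers differ in part from those of the reference annotation used here, so no coordinates are given. Total counts were 18911080 to 24136591 per library, 21778 to 22738 genes had a count above 0, and mitochondrially encoded genes took 1.71% to 5.10% of the counts. Every one of 45 replicate pairs differed beyond sampling noise (chi-square per gene of 9.04 to 149), so no library was counted as a copy of another. The first 4 principal components held 24.0%, 18.7%, 10.3% and 5.94% of the variance.

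Genes were tested with edgeR 4.0.16 in R 4.3.3. Low genes were removed with filterByExpr (minimum count 10, minimum total count 15), libraries were scaled by TMM, and the quasi-likelihood F test was fitted to all 18 libraries with 1 term per group, so that the 3 groups shared 1 estimate of the spread. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all 16738 genes tested were called. The same scripts were tested on simulated counts drawn from the libraries' means and sizes: of genes changed 1.25-fold, 4.00%, 6.12% and 4.08% were recovered in CSDS against control, exercise against CSDS and exercise against control, and of genes changed 3-fold 95.9%, 91.8% and 81.6% (16572, 16541 and 16573 genes tested). A prior count of 2 was used for log2 CPM.

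Before the data were examined, 55 gene lists (pathways, cell types and neighbouring brain regions), the groups, the tests, the alternatives and the rule for named genes were fixed. By that rule the text may name, for each comparison, up to 12 called genes in each direction with the largest fold change and a mean of at least 1 CPM, leaving out predicted genes; where fewer than 10 genes pass, the 10 with the smallest p; up to 4 members of each list with the smallest p; up to 12 genes that pass in the first 2 comparisons with opposite signs and 6 with the same sign; and 10 fixed genes, Bdnf, Fkbp5, Nr3c1, Sgk1, Fos, Npas4, Dcx, Gfap, Ttr and Mbp, whatever their values. Genes named outside it were chosen after their values were seen and are said to be. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, two-sided and adjusted over the 55 lists, and again with an estimated correlation and with fry. The count of members passing was also taken with p-values adjusted over the list alone. These p-values were not adjusted for the number of lists, so some of the 55 can hold passing members by chance. The mean z-score of a list in each mouse was compared by an exact two-sided permutation test over all 924 regroupings of 6 against 6 mice, whose smallest possible p is 0.00216.

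Alternatives fixed in advance were DESeq2 1.42.0, limma voom with quality weights, RLE or plain library size scaling, no filter or a filter of 1 CPM in 6 libraries, the replicate number as a block, only the groups compared, 1 surrogate variable (sva 3.50.0), a 1.5-fold minimum and leaving out each library. Added after seeing the data were settings without control replicate 2 combined with others, covariates for choroid plexus and thalamic levels, robust edgeR estimation, counts of immediate early genes under each setting, and a GC correction. For the GC correction, each library's deviation from the mean was smoothed on the median GC content of a gene's transcripts in the GENCODE M21 set, and the smooth entered the model as an offset; 98.1% of the tested genes had a GC value. On simulated counts with a GC trend and 2-fold changes in exercise against CSDS (16738 genes), the correction raised recovery from 71.5% to 74.0% and lowered false calls from 33 to 1.

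The first 2 comparisons share the CSDS libraries, so their correlation and overlap were set beside 20 simulations of unchanged groups sharing those libraries, and were recomputed with the CSDS libraries split into 3 and 3 in all 20 ways. For each comparison, 100 of the 462 splits of its 12 libraries into 2 groups of 6, the real one included, were refitted. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 (numpy 2.4.6).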

Results

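RNA from the hippocampus of adolescent male C57BL/6J mice was sequenced in 18 libraries, each from 1 mouse, with 6 mice in each of 3 groups. Control mice received no treatment. Another group went through chronic social defeat stress (CSDS), a model of depression in which a mouse repeatedly meets an aggressive resident. The last group went through CSDS and also trained aerobically, starting 1 week before the defeat and continuing through it. The total estimated count per library lay between 18911080 and 24136591, and 16738 genes had enough counts to be tested. At this size, edgeR recovered 70.0%, 76.0% and 74.0% of genes with a simulated 2-fold change in CSDS against control, exercise against CSDS and exercise against control, and 34.7%, 38.0% and 22.4% of those with a 1.5-fold change. The simulated counts were drawn independently for each gene, without structure shared between samples, so recovery in the real libraries may differ. Values below are counts scaled to library size (CPM) as mean ± SD with n = 6, and log2 fold changes carry their SE.

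Regional markers were measured first, since they show which part of the tissue a library holds. In 17 of the 18 libraries the mean level of 26 dentate gyrus granule cell markers lay between 4.82 and 5.36 log2 CPM, and that of 22 neocortical neuron markers between 3.77 and 4.41. Control replicate 2 lay at 3.55 and 5.34. Prox1, a transcription factor of dentate granule cells, was at 10.4 CPM there against 83.5 to 145 CPM in the other 17 libraries, and C1ql2, a secreted protein of the same cells, at 0.408 CPM against 40.7 to 142 CPM. Lamp5, a membrane protein of cortical neurons, was at 259 CPM against 25.7 to 42.8 CPM, and Tbr1, a transcription factor of deep cortical layers, at 164 CPM against 29.4 to 58.9 CPM. These 4 genes were chosen after their values were seen, as were all genes said below to lie outside the rule for named genes. Control replicate 2 was kept in the comparisons, and the edgeR, DESeq2 and list counts were repeated without it.

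**Figure D1:**
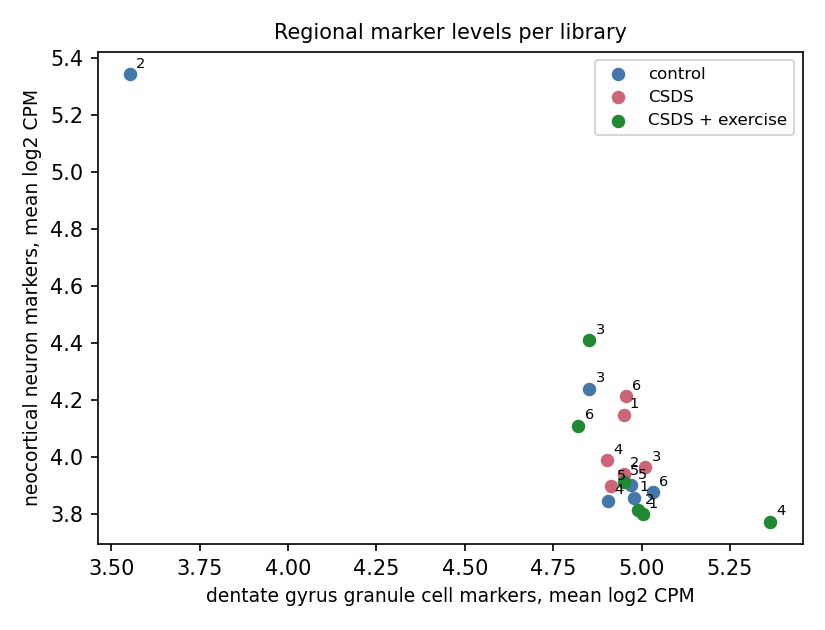
Mean log2 CPM of 26 dentate gyrus granule cell markers (x axis) and 22 neocortical neuron markers (y axis) in each of the 18 libraries, coloured by group and numbered by replicate. Control replicate 2 lies at 3.55 and 5.34, and the other 17 libraries lie between 4.82 and 5.36 on the x axis and between 3.77 and 4.41 on the y axis.

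The first comparison, CSDS against control, asked which hippocampal genes follow repeated defeat. Sgk1, a kinase induced by glucocorticoids, was at 86.4 ± 18 CPM in CSDS mice and at 151 ± 32.3 CPM in controls (log2 fold change -0.81 ± 0.18). Zbtb16, a transcription factor induced by the same hormones, was at 66.1 ± 9.99 against 42.0 ± 9.25 CPM (0.65 ± 0.17). Among 27 glucocorticoid-responsive genes, Zbtb16 rose and Sgk1 fell when adjusted over the list alone. None passed over all genes tested (adjusted p = 0.993 for Zbtb16 and Sgk1). Here and below, adjustment over a list alone does not allow for the 55 lists examined, so some can hold passing members by chance. Fos, a transcription factor made within minutes of neuronal activity, was at 8.78 ± 3.50 against 20 ± 14.6 CPM (-1.19 ± 0.36). Nr4a1, a nuclear receptor with the same kinetics, was at 42.9 ± 10.5 against 77.4 ± 38.2 CPM (-0.85 ± 0.26), and the small GTPase gene Arl4d at 9.34 ± 1.61 against 18.1 ± 8.37 CPM (-0.96 ± 0.24). These 3 of 32 immediate early genes fell when adjusted over the list alone and 0 over all genes. Without control replicate 2 the count over the list was 0, as it was without control replicate 3 or CSDS replicates 1, 4 or 6.

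Over all genes, edgeR called 0 genes between CSDS and control, with 588 at an unadjusted p under 0.05 (307 higher, 281 lower). Here 5% of the genes tested make 837, but the other splits of these libraries had a median of 499. DESeq2, run without the filter on low counts, called 1, the predicted gene Gm5124, which lies outside the rule for named genes. Its log2 fold change of -22.4 (adjusted p = 2.1e-05) is too extreme for its size to be relied on. Limma voom called 0, with 3269 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.13. The genes with the smallest p included Msl3l2, at 21.2 ± 1.54 against 15.6 ± 2.62 CPM (0.44 ± 0.10), whose counts can be shared with its parent gene and are uncertain. Plekhf1, an endosomal protein, was at 4.44 ± 0.707 against 6.87 ± 1.36 CPM (-0.63 ± 0.15), and Emid1, an extracellular matrix protein, at 4.52 ± 0.835 against 2.86 ± 0.544 CPM (0.66 ± 0.17). All 3 had an adjusted p of 0.993. Bdnf, a neurotrophin of hippocampal neurons, was at 27.3 ± 4.50 against 24.7 ± 6.05 CPM (0.15 ± 0.15). Fkbp5, a chaperone that restrains the glucocorticoid receptor, was at 98.9 ± 10.8 against 81.3 ± 24.9 CPM (0.28 ± 0.19), and Nr3c1, the receptor itself, at 64.7 ± 9.52 against 76.6 ± 23.3 CPM (-0.25 ± 0.16). Npas4 (-0.28 ± 0.30), Dcx (0.02 ± 0.14), Gfap (0.30 ± 0.25), Ttr (-0.24 ± 1.32) and Mbp (-0.11 ± 0.15), which mark active neurons, newborn neurons, astrocytes, choroid plexus and myelin, did not pass either.

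Of 55 gene lists fixed before the data were examined, camera with its preset correlation called 20 between CSDS and control (11 higher, 9 lower). With an estimated correlation 0 held, and the smallest adjusted p was 0.606. Interferon-stimulated genes, which respond to viral and inflammatory signals, had a positive log2 fold change in 28 of 29 members (median 0.32, camera adjusted p = 2.66e-06, adjusted p = 0.667 with an estimated correlation). No member passed when adjusted over the list alone or over all genes. Mx2 was at 1.35 ± 0.537 against 0.669 ± 0.199 CPM (1.01 ± 0.28), Irf7 at 10.2 ± 6.71 against 5.36 ± 2.74 CPM (0.93 ± 0.46), Ifit1 at 4.32 ± 2.70 against 2.57 ± 1.15 CPM (0.75 ± 0.38) and Cxcl10 at 0.805 ± 0.993 against 0.369 ± 0.168 CPM (1.11 ± 0.57). The antigen-presenting chaperone Cd74 was at 4.78 ± 2.33 against 8.40 ± 2.79 CPM (-0.82 ± 0.30).

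Adult neurogenesis and immature neuron genes were on the higher side in CSDS mice in 24 of 31 members (median 0.20, camera adjusted p = 2.96e-06, adjusted p = 0.606 with an estimated correlation). The proliferation marker Mki67 was at 2.5 ± 0.414 against 1.72 ± 0.758 CPM (0.53 ± 0.25) and the stem cell factor Sox2 at 35.9 ± 2.96 against 31.7 ± 2.86 CPM (0.18 ± 0.08). GABAergic interneuron genes had a median of 0.13 with 18 of 28 members on the higher side (camera adjusted p = 0.0232, adjusted p = 0.606 with an estimated correlation). Among them, the interneuron transcription factor Dlx1 was at 26.2 ± 4.23 against 19.4 ± 3.40 CPM (0.43 ± 0.14) and the secreted glycoprotein Reln at 76.3 ± 17.8 against 58.6 ± 10.2 CPM (0.38 ± 0.15). In exact permutation tests of the level per mouse, the list p was 0.0281 for neurogenesis genes and 0.0108 for interneuron genes, and neither held after adjustment over the 55 lists. Without control replicate 2, the same test gave an unadjusted p of 0.0519 for neurogenesis genes and 0.00866 for interneuron genes. Collagen and basement membrane genes had a median of 0.20 over 63 members (camera adjusted p = 6.11e-06, adjusted p = 0.697 with an estimated correlation), with Col7a1 at 0.85 ± 0.28 and Col16a1 at 0.66 ± 0.25 on the log2 scale. Meningeal and vascular fibroblast genes, which make collagens, were on the higher side too in 23 of 29 members (median 0.18, camera adjusted p = 0.000578, adjusted p = 0.718 with an estimated correlation), and were not called without control replicate 2 (adjusted p = 0.119). The interneuron median was 0.08 after GC correction. No member of these 4 lists passed when adjusted over the list alone or over all genes.

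Thalamic neuron markers had a median of -0.69, negative in 18 of 19 members (camera adjusted p = 1.77e-06, adjusted p = 0.606 with an estimated correlation). For both genes named here the SD in controls exceeded the mean. Tnnt1 was at 1.38 ± 0.125 CPM in CSDS mice and at 9.67 ± 12.7 CPM in controls (-2.80 ± 0.87), and Tcf7l2, a transcription factor of thalamic neurons, at 4.80 ± 0.671 against 20.3 ± 26.1 CPM (-2.07 ± 0.88). Endothelial and blood-brain barrier genes had a median of -0.16 over 27 members (camera adjusted p = 6.38e-05, adjusted p = 0.606 with an estimated correlation). The organic anion transporter Slco1a4 was at 37.4 ± 6.34 against 52.2 ± 10.5 CPM (-0.48 ± 0.14). Neither list held a member that passed when adjusted over the list alone or over all genes.

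The second comparison, exercise with CSDS against CSDS alone, asked which genes training alters in stressed mice. Several genes of antigen presentation were lower in the trained mice. H2-K1, a class I molecule that displays peptides on the cell surface, was at 38.0 ± 7.74 CPM in trained and at 61.8 ± 14.8 CPM in untrained CSDS mice (-0.70 ± 0.19). H2-D1 was at 52.9 ± 13.8 against 86.0 ± 26.4 CPM (-0.70 ± 0.21), H2-T23 at 10.8 ± 1.67 against 16.9 ± 4.50 CPM (-0.64 ± 0.19) and H2-Q7 at 2.01 ± 0.610 against 5.32 ± 3.20 CPM (-1.40 ± 0.42). They were among 7 of 19 members that fell when adjusted over the list alone, with 0 over all genes. Counts of these near-identical genes can be shared among them and are uncertain. The list was called by camera (median -0.34, adjusted p = 0.000254, adjusted p = 0.982 with an estimated correlation). Its members had a median GC content of 55.5%, and after the GC correction described below the median log2 fold change was -0.20 (adjusted p = 0.000141).

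Interferon-stimulated genes were on the lower side in trained mice in 28 of 29 members (median -0.55, camera adjusted p = 3.49e-07, adjusted p = 0.982 with an estimated correlation). Mx2, an antiviral GTPase, fell from 1.35 ± 0.537 to 0.622 ± 0.151 CPM (-1.11 ± 0.28) and Irf7, a transcription factor that amplifies interferon signalling, from 10.2 ± 6.71 to 3.38 ± 1.19 CPM (-1.59 ± 0.47), when adjusted over the list alone, and neither passed over all genes (adjusted p = 0.198 for both). Oasl2 had a log2 fold change of -1.01 ± 0.36 and Irf9 of -0.80 ± 0.29, and neither passed. In an exact permutation test of the level per mouse, the list p was 0.126 for interferon-stimulated and 0.0779 for antigen presentation genes. The CSDS mice spread widely, from 1.70 to 3.21 log2 CPM for the interferon list, while the trained mice lay between 1.47 and 2.48.

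**Figure D2:**
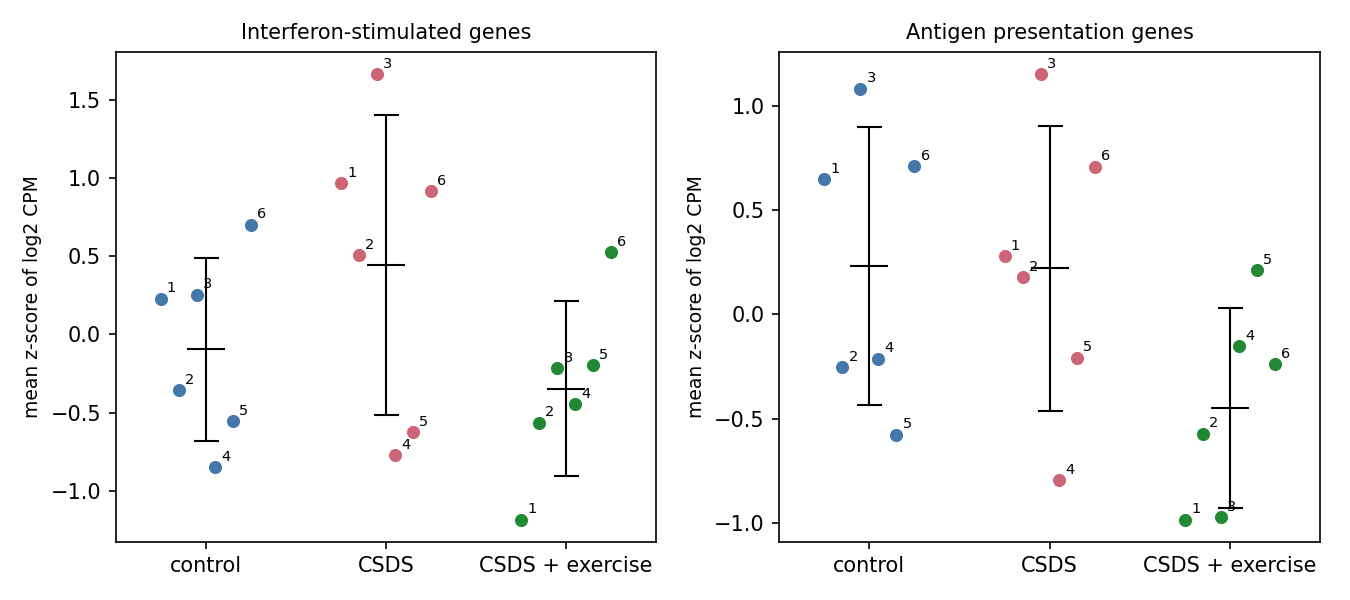
Mean z-score of log2 CPM over the measured members of 2 gene lists, interferon-stimulated genes (29 members, left) and antigen presentation genes (19 members, right), for each mouse, numbered by replicate. Bars give the mean and SD of the 6 mice of a group. Group means were -0.10, 0.44 and -0.35 on the left and 0.23, 0.22 and -0.45 on the right for control, CSDS and CSDS with exercise, and the groups overlap in both panels.

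Over all genes, edgeR called 0 genes between trained and untrained CSDS mice, and the smallest adjusted p was 0.0855. An unadjusted p under 0.05 was found for 2604 genes (1355 higher, 1249 lower). For comparison, 5% of the genes tested make 837, and the other splits of these libraries had a median of 436. DESeq2 called 164 genes (42 higher, 122 lower) and limma voom with quality weights 5567 (2578 higher, 2989 lower). Both the GC correction described below and the splits counted genes with edgeR alone. The DESeq2 and limma voom counts of any comparison were therefore not set against either. The smallest p belonged to the predicted gene Gm37421, at 1.79 ± 0.914 CPM in trained mice and 0.00761 ± 0.0186 CPM in untrained ones, where 5 of the 6 libraries had no count. It was followed by the predicted gene Gm29216, at 3.93 ± 4.97 against 168 ± 119 CPM (-5.40 ± 0.96, adjusted p = 0.143). Counts of such predicted genes can be split with near-identical copies and are uncertain. Klf15, a metabolic transcription factor induced by glucocorticoids, was at 17.3 ± 1.93 against 25.9 ± 4.2 CPM (-0.59 ± 0.12, adjusted p = 0.143). Ddah2, an enzyme of methylarginine breakdown (-0.51 ± 0.10), Hspbp1, a cofactor of the chaperone Hsp70 (-0.38 ± 0.08), and Akt1s1, an inhibitory subunit of mTOR complexes (-0.53 ± 0.11), had the same adjusted p. Over 28 alternative settings, GC correction included, the log2 fold change ran from -0.64 to -0.08 for Akt1s1 and -0.44 to -0.05 for Hspbp1. It ran from -0.58 to -0.24 for Ddah2 and -0.67 to -0.44 for Klf15.

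The size of these differences followed the GC content of the transcripts. Across genes, which are not independent replicates, the log2 fold change of exercise against CSDS had a Pearson correlation of -0.54 with transcript GC content. The genes at an unadjusted p under 0.05 had a median GC content of 43.8% on the higher and 58.0% on the lower side, against 50.5% for all genes. The slope of a library's gene levels on GC content, in log2 units per 10 points, was 0.12 ± 0.18 in CSDS and -0.16 ± 0.21 in trained mice (exact permutation p = 0.0238), and 0.05 ± 0.15 in controls. With each library's trend removed, 938 genes had an unadjusted p under 0.05, or 1762 without exercise replicate 4. Without exercise replicate 4, whose slope of 0.19 was the only positive one among trained mice, edgeR called 625 genes (144 higher, 481 lower), with a median GC content of 42.0% and 59.1%. After GC correction those 625 calls were 0 (smallest adjusted p = 0.0586). Without CSDS replicate 5 edgeR called 43.

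**Figure D3:**
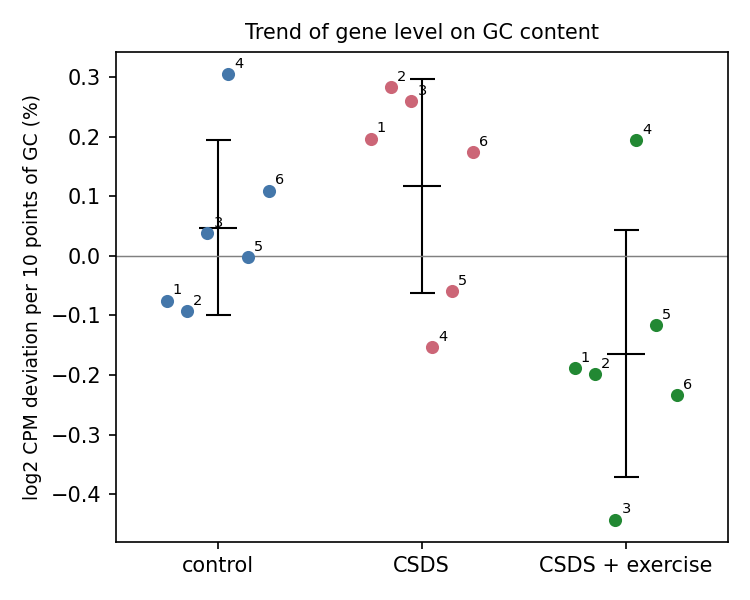
Slope of each library's gene levels on transcript GC content, as the deviation of log2 CPM from the mean of all libraries per 10 percentage points of GC content (y axis), by group and numbered by replicate. Bars give the mean and SD of 6 libraries; 5 of the 6 trained mice lie below 0, and exercise replicate 4 lies at 0.19.

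The GC correction also bore on cell type markers. Tmem119, a microglial membrane protein, fell from 31.6 ± 3.62 to 22.9 ± 2.43 CPM when adjusted over the microglia list alone (-0.47 ± 0.10, adjusted p = 0.147 over all genes), and no other member of that list passed. Slc32a1, the vesicular GABA transporter, was at 78.5 ± 7.59 against 110 ± 14 CPM (-0.48 ± 0.10). With Npas1 (-0.71 ± 0.22) and Dlx5 (-0.61 ± 0.19), transcription factors of interneurons, it was among 6 of 28 GABAergic interneuron genes that fell when adjusted over the list alone, 0 over all genes. That list was called lower (median -0.10, camera adjusted p = 0.0199, adjusted p = 0.982 with an estimated correlation), and was no longer called after GC correction (adjusted p = 0.053) or without exercise replicate 4 (adjusted p = 0.307). After GC correction the log2 fold change was -0.15 for Tmem119, -0.11 for Slc32a1 and -0.09 for Hspbp1, against -1.37 for Irf7, -1.16 for Mx2, -0.55 for H2-K1 and -0.47 for Klf15.

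Of the 55 lists, camera called 11 between trained and untrained CSDS mice (4 higher, 7 lower), and 0 held with an estimated correlation. Mitochondrially encoded genes were on the higher side in 12 of 13 members (median 0.43, camera adjusted p = 0.00388, adjusted p = 0.982 with an estimated correlation). In it mt-Atp6, a subunit of ATP synthase, was at 350 ± 134 against 172 ± 89.7 CPM (1.03 ± 0.36), and the call was lost after GC correction (adjusted p = 0.636). GABA receptor genes were on the higher side in 18 of 19 members (median 0.24, camera adjusted p = 0.0096, adjusted p = 0.982 with an estimated correlation). Gabra4, a subunit of extrasynaptic receptors, rose from 65.6 ± 10.9 to 94.8 ± 24.0 CPM when adjusted over that list alone (0.53 ± 0.15), not over all genes, and the list was no longer called after GC correction (adjusted p = 0.187). Collagen and basement membrane genes were on the lower side in 53 of 63 members (median -0.38, camera adjusted p = 1.5e-05, adjusted p = 0.982 with an estimated correlation), with Col4a1 of vascular basement membranes at -0.55 ± 0.22 and the fibrillar collagen gene Col1a1 at -0.87 ± 0.36. After GC correction the collagen median was -0.23. Meningeal and vascular fibroblast genes were lower alongside in 27 of 29 members (median -0.32, camera adjusted p = 0.000598, adjusted p = 0.982 with an estimated correlation), with a median of -0.26 after GC correction. Thalamic markers had a median of 1.04 (camera adjusted p = 0.00353, adjusted p = 0.982 with an estimated correlation). The call rested on exercise replicate 6, where Tcf7l2 was at 143 CPM against 4.63 to 33.3 CPM in the other trained mice, and without that replicate the adjusted p was 0.334.

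Immediate early genes were on the lower side in 27 of 32 members in trained against untrained CSDS mice (median -0.24, camera adjusted p = 0.000617, adjusted p = 0.982 with an estimated correlation), with 0 members passing when adjusted over the list alone or over all genes. Over the list alone 18 passed with limma voom and 3 without exercise replicate 4. After GC correction the median was -0.12 (adjusted p = 0.015), and -0.22 without exercise replicate 4 as well. Junb was at 35.6 ± 12.4 against 57.6 ± 14.8 CPM (-0.69 ± 0.22), Fos at 6.63 ± 1.60 against 8.78 ± 3.50 CPM (-0.40 ± 0.37) and Npas4 at 5.08 ± 1.57 against 7.23 ± 2.00 CPM (-0.51 ± 0.31). Dcx, a protein of newborn neurons, was at 16.4 ± 2.92 against 12.9 ± 2.08 CPM (0.35 ± 0.14, adjusted p = 0.253). Its log2 fold change ran from 0.09 to 0.44 over 28 alternative settings, GC correction included. Bdnf (0.14 ± 0.15), Fkbp5 (-0.11 ± 0.19), Nr3c1 (0.28 ± 0.16), Sgk1 (-0.12 ± 0.18), Gfap (-0.14 ± 0.25), Ttr (-0.33 ± 1.32) and Mbp (-0.14 ± 0.15) did not pass.

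The last comparison set trained CSDS mice against unstressed controls. Of 32 immediate early genes, which neurons switch on with activity, 27 had a negative log2 fold change and 15 fell when adjusted over the list alone, with 0 over all genes. Fos was at 6.63 ± 1.60 against 20 ± 14.6 CPM (-1.59 ± 0.37, adjusted p = 0.146 over all genes). Egr2, a zinc finger transcription factor, was at 1.09 ± 0.444 against 5.57 ± 5.05 CPM (-2.34 ± 0.50), Arl4d at 8.22 ± 2.23 against 18.1 ± 8.37 CPM (-1.14 ± 0.24) and Junb at 35.6 ± 12.4 against 69.9 ± 19.3 CPM (-0.97 ± 0.22). Npas4, induced by calcium entry, was also among the 15 (-0.79 ± 0.31).

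The immediate early gene list had a median of -0.46 and was called by camera (adjusted p = 2.1e-13, adjusted p = 0.632 with an estimated correlation). Its level per mouse differed with an exact permutation p = 0.00866, which was 0.476 after adjustment over the 55 lists. Without control replicate 2, the library with neocortical markers, 8 members fell over the list alone with an exact permutation p = 0.0173, and Fos and Egr2 had log2 fold changes of -1.11 and -1.70. The count was 9 without exercise replicate 1 and 9 without exercise replicate 2. After GC correction 10 members fell (list median -0.40), and with both changes 6 did (-0.20). The median was -0.34 without control replicate 2 alone, and -0.19 with 1 surrogate variable as well.

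**Figure D4:**
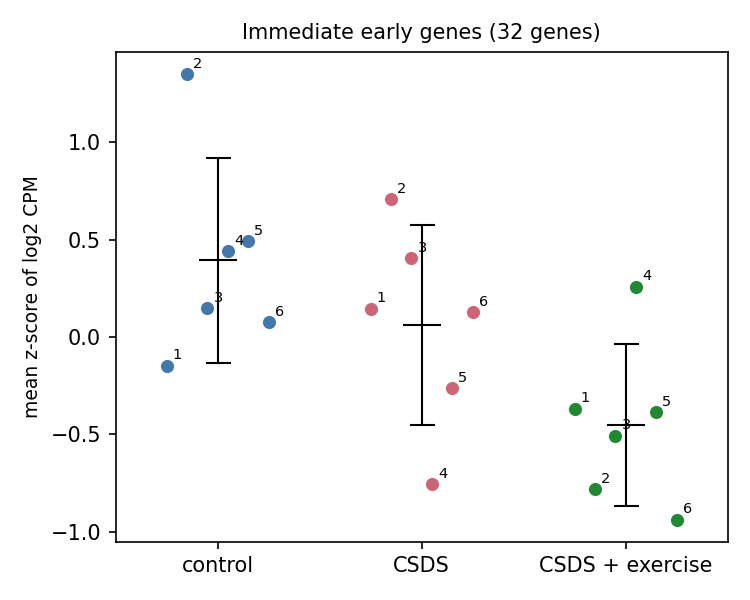
Mean z-score of log2 CPM over 32 immediate early genes for each mouse, by group and numbered by replicate, with bars for the mean and SD of 6 mice. Control replicate 2 has the highest level, at 1.35, and 5 of the 6 trained mice lie below every control mouse, at -0.37 or lower; exercise replicate 4 lies at 0.26.

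Over all genes, edgeR called 3 genes between trained CSDS and control mice, where 1874 had an unadjusted p under 0.05 (1139 higher, 735 lower). For comparison, 5% of the genes tested make 837, and the other splits of these libraries had a median of 743. Plekhf1 (ENSMUSG00000074170), an endosomal protein that binds phosphoinositides, fell from 6.87 ± 1.36 to 3.55 ± 0.619 CPM (-0.95 ± 0.16). The predicted genes Gm42664 and Gm48415 rose from 0.190 ± 0.0909 to 0.911 ± 0.458 CPM (2.23 ± 0.36) and from 3.22 ± 0.301 to 6.01 ± 1.11 CPM (0.90 ± 0.15). All 3 had an adjusted p of 0.0454. DESeq2 called 109 genes (78 higher, 31 lower) and limma voom 183 (128 higher, 55 lower). These calls were close to the threshold. Without control replicate 2 the adjusted p of all 3 was 0.126 and 0 genes were called. After GC correction it was 0.109 for Plekhf1 (-0.90 ± 0.16), 0.184 for Gm42664 (1.87 ± 0.37) and 0.377 for Gm48415 (0.56 ± 0.15), with 1172 genes at an unadjusted p under 0.05. Leaving out 1 library gave 13 genes without exercise replicate 4, 3 without control replicate 6 (Plekhf1, Gm48415 and Atp5d), 3 without exercise replicate 3 (Gm42664, Gm21781 and Gm3764), 2 without exercise replicate 5 (Sgk1 and Gm44660), and 0 without any of the others. Of these, only Gm44660 lies outside the rule for named genes.

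Some genes with a small p did not pass over all genes tested. Malat1, a long nuclear noncoding RNA, was at 250 ± 86.7 against 114 ± 24.5 CPM (1.14 ± 0.21, adjusted p = 0.0699). The imprinted transcript Kcnq1ot1 was at 7.97 ± 2.66 against 3.97 ± 0.388 CPM (1.00 ± 0.18, adjusted p = 0.063) and Snhg14, a host of small nucleolar RNAs, at 37.1 ± 12.4 against 19.6 ± 1.95 CPM (0.92 ± 0.18, adjusted p = 0.0827). Grin2a and Grin2b, subunits of the NMDA receptor, were at 355 ± 45.7 against 255 ± 30.9 CPM (0.48 ± 0.10, adjusted p = 0.116) and 627 ± 79.5 against 462 ± 77.3 CPM (0.44 ± 0.11). Vcan, a proteoglycan of the extracellular matrix, was at 19.4 ± 1.92 against 14.6 ± 1.71 CPM (0.41 ± 0.11). Adjusted over the list alone, Grin2a and Grin2b rose among 45 glutamate receptor and postsynaptic density genes. Vcan rose in the same way in the oligodendrocyte precursor and perineuronal net lists. None of these lists was called by camera. The genes at an unadjusted p under 0.05 had a median GC content of 44.1% on the higher and 57.2% on the lower side in this comparison too, and after GC correction Malat1 had a log2 fold change of 0.92 (adjusted p = 0.184).

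Glucocorticoid-responsive genes fell in 3 of 27 members when adjusted over the list alone and in 0 over all genes. This was the only list called by fry for changes in either direction (adjusted p = 0.032). Sgk1 was at 79.5 ± 22.0 against 151 ± 32.3 CPM (-0.93 ± 0.18, adjusted p = 0.0827 over all genes). Nfkbia, the inhibitor of NF-kB, was at 17.2 ± 4.40 against 25.1 ± 3.92 CPM (-0.54 ± 0.15) and Arrdc2, an arrestin-like protein, at 8.89 ± 2.11 against 13.5 ± 2.83 CPM (-0.60 ± 0.17). The clock gene Per1, which also responds to glucocorticoids, was at 69.4 ± 17.4 against 97.1 ± 19 CPM (-0.48 ± 0.17). The list was called lower (median -0.19, camera adjusted p = 0.0181, adjusted p = 0.904 with an estimated correlation), and was not called without control replicate 3 (adjusted p = 0.17) or exercise replicate 4 (adjusted p = 0.268).

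Antigen presentation genes had a negative log2 fold change in 19 of 19 members (median -0.45, camera adjusted p = 1.5e-05, adjusted p = 0.904 with an estimated correlation), with 0 members passing when adjusted over the list alone or over all genes. H2-T23 was at 10.8 ± 1.67 against 16.1 ± 4.49 CPM (-0.57 ± 0.19), H2-K1 at 38.0 ± 7.74 against 53.3 ± 13.7 CPM (-0.49 ± 0.19) and H2-D1 at 52.9 ± 13.8 against 73.1 ± 16.1 CPM (-0.47 ± 0.21). Tmem119 was at 22.9 ± 2.43 against 28.6 ± 2.93 CPM (-0.32 ± 0.10). Across genes, the log2 fold changes of this comparison had a Pearson correlation of -0.44 with transcript GC content. Over 28 alternative settings, GC correction included, the log2 fold change ran from -0.41 to -0.09 for Tmem119. It ran from -0.66 to -0.33 for H2-T23, -0.58 to -0.40 for H2-K1 and -0.64 to -0.36 for H2-D1. Choroid plexus genes had a median of -0.61 (camera adjusted p = 0.000577, adjusted p = 0.919 with an estimated correlation), which was not called without exercise replicate 4 (adjusted p = 0.263). Ttr was at 2117 ± 2535 against 3151 ± 1809 CPM (-0.57 ± 1.32). Ependymal and motile cilia genes had a median of 0.31 (camera adjusted p = 0.0359, adjusted p = 0.919 with an estimated correlation; adjusted p = 0.981 without control replicate 2), with Sntn at 1.41 ± 0.51. The smooth muscle gene Cnn1 was at -1.24 ± 0.38 in a pericyte and smooth muscle list with a median of -0.18 (camera adjusted p = 0.0302, adjusted p = 0.904 with an estimated correlation). After GC correction that list was no longer called (median -0.09, adjusted p = 0.11; median -0.18, adjusted p = 0.0929 without exercise replicate 4 as well).

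Of the 55 lists, camera called 11 between trained CSDS and control mice (2 higher, 9 lower), and 0 held with an estimated correlation. Among the 11, neocortical neuron markers were lower (median -0.34, camera adjusted p = 0.0262) and dentate gyrus granule cell markers higher (median 0.20, camera adjusted p = 0.0303). Control replicate 2 stood apart from all other libraries on both of these lists. Dcx was at 16.4 ± 2.92 against 12.7 ± 2.17 CPM (0.37 ± 0.14, adjusted p = 0.33) and Bdnf at 30.1 ± 4.21 against 24.7 ± 6.05 CPM (0.29 ± 0.15, adjusted p = 0.483). Fkbp5 (0.18 ± 0.19), Nr3c1 (0.03 ± 0.16), Gfap (0.16 ± 0.25) and Mbp (-0.25 ± 0.15) did not pass.

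Whether training opposed the effect of defeat was examined by setting the first 2 comparisons side by side. In edgeR, 0 genes passed in both with opposite signs, and 0 did in simulated groups without effects. Since edgeR called 0 genes in each of the 2 comparisons, that overlap could only be 0 and decides nothing. At an unadjusted p under 0.05 in both, 96 genes were higher with CSDS and lower with training, where simulation gave 75 (range 59 to 92) and independent lists 22.9. Conversely, 74 were lower with CSDS and higher with training, where simulation gave 97.2 (range 80 to 117) and independent lists 22.7. Another 12 had the same sign in both, where simulation gave 1 (range 0 to 4). The Pearson correlation of the log2 fold changes across genes, which are not independent replicates, was -0.47, against a mean of -0.50 (range -0.53 to -0.46) in 20 simulations in which only the CSDS libraries were shared. The covariance was -0.0423 against a simulated -0.0336 (range -0.0354 to -0.0305). When the real libraries were regrouped, the correlation ran from -0.73 to -0.01, a wider range than the simulated one. The simulated ranges may therefore be too narrow, so a count or covariance outside them does not exclude chance. With the CSDS libraries split into 3 and 3, so that no library served both comparisons, the correlation had a median of -0.18 (range -0.29 to 0.04) over 20 splits, and the covariance a median of -0.0213.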

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

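The tests of explanations in this part were chosen after the result they bear on was seen. Only the one on transcript length was written down before its own outcome was known. Gene counts without control replicate 2 and with a replicate block, also used here, come from settings fixed in advance. So does the exact permutation test of list levels on all libraries. Among 306 groups of 6 values (65 genes, 28 lists and 9 library measures in 3 groups), 41 held a library whose gap to its nearest neighbour, as a share of the whole range, lay above Dixon's critical value, where chance gives 15.3, and 13 of the 41 were in control replicate 2.

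In control replicate 2, Fkbp5 was at 34.2 CPM (other controls 79.4 to 106) and Nr3c1 at 124 (62.4 to 72.2). Fos was at 48.7 (9.15 to 20.6), Npas4 at 20.1 (5.73 to 7.73), Nr4a1 at 153 (47.5 to 75.6) and Egr2 at 15.5 (1.49 to 5.46). The list levels of that library, as mean z-scores, were 1.59 for circadian clock genes (-0.16 to 0.25 in the other controls), -1.72 for choroid plexus genes (0.31 to 1.07) and -2.43 for ependymal and motile cilia genes (-0.28 to 0.68). They were -1.61 for dentate gyrus granule cell markers (-0.15 to 0.14) and 1.73 for neocortical neuron markers (-0.47 to 0.19). Its median rank correlation with the other controls was 0.966 (0.980 to 0.987), and its score on the second principal component -46.5 (0.385 to 15.0).

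The pattern of that library is a loss of hippocampal markers with a gain of neocortical ones. Of all 18 libraries it was lowest for 15 of 26 dentate gyrus markers (1.44 by chance) and highest for 12 of 22 neocortical markers (1.22 by chance). It was also lowest for 13 of 20 CA1 markers and 12 of 24 CA3 and CA2 markers, and highest for 3 and 4 of them. The median log2 difference from the other controls was -1.28 for CA1 markers and -0.77 for CA3 and CA2 markers. A GC trend of the library is argued against, since the neocortical minus the dentate gyrus difference from the other controls was 2.08 on the log2 scale before GC correction and 2.13 after it. A swap with a mouse of another group is left open. In the other groups 0 libraries had a dentate gyrus level nearer to this one than to the other controls, but this cannot decide the point. A swapped library could be the only one with such tissue. A dissection that took neocortex in place of much of the hippocampus remains a candidate explanation, and so does a tube from outside the study, which was not tested. A first test on the median dentate gyrus difference (-0.76, or -0.69 after GC correction) decided nothing. After that value was seen, it was replaced by the counts of dentate gyrus and neocortical markers. The bound of 5 times chance for them was set with the counts in view. No biological explanation was tested.

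The number of genes at an unadjusted p under 0.05 in exercise against CSDS, 2604 where 5% of the genes tested make 837, was reached in 7 of 100 splits of the libraries (4232 in the highest other split), so chance is not excluded for it. After GC correction 938 genes were left, under the 1255 that make 1.5 times those 837, so a GC trend per library could account for much of the difference. That bound was not met without exercise replicate 4, where 4441 genes were at that p before GC correction and 1762 after it, so a part is left open. The count was 2395 after a correction for transcript length, which argues against length as the main source. It was 2377 with the choroid plexus and thalamic levels as covariates and control replicate 2 left out. No count without that library alone was taken to set beside it, so neighbouring tissue stays open. After GC correction, leaving out that library moved the count from 938 to 1194. Whether the GC trend arose in library preparation or RNA handling, or whether exercise itself shifted genes that differ in GC content, stays open. The GC correction removes either.

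Immediate early genes were lower in exercise against control, with 15 of 32 members passing when adjusted over the list alone. The tissue of control replicate 2, where 17 of the 32 were highest of all 18 libraries, is argued against as the whole source, since 8 members passed without that library, and so is a GC trend, since 10 passed after correction; 6 passed with both changes. Part of the size does depend on that library, with a log2 fold change for Fos of -1.59 with it and -1.11 without it. The time between handling and dissection, which these genes follow closely, was not tested, and defeat with exercise remains an open explanation that may account for the difference.

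Other splits of the 12 libraries of each comparison into 6 and 6, of which 100 were drawn, excluded chance for no result. A real count of 0 is reached by every split, so the splits decide nothing for genes called by edgeR in CSDS against control (0 genes, 385 in the highest other split, 100 of 100 as many) and exercise against CSDS (0, 671, 100 of 100), or for immediate early genes in exercise against CSDS (0, 8, 100 of 100). For genes called in exercise against control few splits gave as many (3, 35 in the highest other split, 3 of 100), but with 0 genes without control replicate 2, with a replicate block and after GC correction, chance stays open there too. Splits that call 385, 671 or 35 genes point to a structure of the samples that the groups do not follow, and what those splits share was not tested. For lists called by camera chance cannot be excluded in any comparison, with 20 lists in CSDS against control (29 in the highest other split, 39 of 100 as many), 11 in exercise against CSDS (25, 85 of 100) and 11 in exercise against control (29, 92 of 100). For immediate early genes passing over the list alone in exercise against control few splits gave as many (15 members, 16 in the highest other split, 2 of 100). With 11 results tested in this way, and an exact permutation p of the list level of 0.476 after adjustment over the lists, chance stays open for them too. In CSDS against control few splits gave as many (3, 4, 3 of 100), but the exact permutation p of the list level was 0.297 and 0 members passed without control replicate 2, so chance stays open. The 1874 genes at an unadjusted p under 0.05 in exercise against control were reached in 12 of 100 splits (4732 in the highest other split). Regrouping all 18 libraries gave 0 genes opposite in the first 2 comparisons in each of 100 draws, which decides nothing beside a real count of 0, and a correlation at least as low as the real -0.47 in 58 of 100, down to -0.73.

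Among other controls, replicate 6 was at 4.79 CPM for Ifit1 (1.63 to 2.62 in the other controls), 1.86 for Gm37421 (0 to 0.545) and 52.6 for Hspbp1 (60.7 to 65.2). Control replicate 1 was at 4.73 for Kcnq1ot1 (3.68 to 3.96), and replicate 4 had a level of -0.75 for GABA receptor genes (-0.08 to 0.22). Among CSDS mice, replicate 6 was at 2.77 CPM for Cxcl10 (0.187 to 0.879) and 16.4 for Arrdc2 (9 to 11.7), and replicate 1 was the only one with a count for Gm37421, at 0.0457 CPM. CSDS replicate 5 had a total count of 19552900 (21535900 to 22383700 in the others), replicate 2 had 21933 genes above 0 (22188 to 22269), and replicate 1 a median rank correlation with its group of 0.992 (0.985 to 0.987).

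Exercise replicate 6 was at 4526 CPM for Mbp (2620 to 3292 in the other trained mice), 5.63 for Irf7 (2.12 to 3.41) and 4.47 for Ifit1 (1.5 to 2.59). It was at 143 for Tcf7l2 (4.63 to 33.3) and 3.12 for Dlx5 (1.53 to 2.11), and had a CA1 pyramidal cell marker level of -0.82 (0.05 to 0.29). Exercise replicate 4 was at 13.7 CPM for Gm29216 (0.611 to 4.49), 42.1 for Akt1s1 (30.3 to 34.5), 27.7 for Tmem119 (20.6 to 22.7) and 59.3 for Junb (24.8 to 36.7). Its list levels were -1.48 for nuclear-encoded oxidative phosphorylation genes (0.21 to 0.64), -1.17 for cytosolic ribosomal protein genes (0.24 to 0.86) and 0.85 for dentate gyrus granule cell markers (-0.09 to 0.22). Exercise replicate 2 was at 417 CPM for Malat1 (174 to 248). Exercise replicate 5 was at 25.4 for Nfkbia (13.1 to 17.4) and 12.9 for Arrdc2 (6.62 to 8.76), and replicate 3 had a neocortical marker level of 0.50 (-0.45 to -0.23).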

How the results depend on the processing

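The settings that combine 2 changes, the covariates, the robust estimation, the counts of immediate early genes and the GC correction were chosen after the data were seen; the other settings were fixed before. Numbers follow the order CSDS against control, exercise against CSDS and exercise against control; edgeR called 0, 0 and 3 genes, camera 20, 11 and 11 lists, and 3, 0 and 15 immediate early genes passed over the list alone. Scaling by library size alone, the 1.5-fold minimum and robust estimation left those of these counts they bear on within 1.5 times. The cause of a change was not tested unless the setting itself gives it, as fewer libraries do.

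DESeq2 called 1, 164 and 109 genes, and 339 and 89 in the last 2 comparisons without control replicate 2. Limma voom called 5567 genes in exercise against CSDS and 183 in exercise against control, with 1 and 18 immediate early genes in the first 2 comparisons. Without a filter on low counts, 2 genes passed in exercise against CSDS (Gm29216 and Gm37421) and 0 in exercise against control, where 17 lists were called; with the stricter filter 0 genes passed there. Using only the groups compared gave 1 gene (Gm37421) in exercise against CSDS, 0 in exercise against control, and 1 and 9 immediate early genes in the comparisons with controls. With 1 surrogate variable, 1 gene (Gm37421) and 19 genes passed in the last 2 comparisons, 0 immediate early genes in the first, and the correlation of the first 2 comparisons was -0.36. Without control replicate 2 as well, 3 (Gm9803, Gm22009 and Gm37421, of which the first pair lies outside the rule for named genes) and 0 genes passed in the last 2, 7 immediate early genes in the last, and the correlation was -0.39. RLE scaling left 1 immediate early gene in CSDS against control.

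With an estimated correlation 0, 0 and 0 lists were called, and likewise 0, 0 and 0 with fry for changes in 1 direction. For changes in either direction, a test taken up after the data were seen, fry called 0, 0 and 1, the glucocorticoid-responsive genes. Splitting the CSDS libraries gave a median correlation of -0.18. With the choroid plexus and thalamic covariates and without control replicate 2, 0 and 1 immediate early genes passed in the first 2 comparisons, 0 genes in the last, and the correlation was -0.27. DESeq2 without control replicate 2 gave 1, 1 and 8 immediate early genes. After GC correction 1 gene (Gm37421) passed in exercise against CSDS and 0 in exercise against control. Without control replicate 2 as well, 0 genes passed in exercise against control, with 1 immediate early gene in the first comparison and 6 in the last. Without exercise replicate 4 instead, 1 gene (ENSMUSG00000121345) passed in exercise against control.

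The replicate numbers did not pair the mice: of 6 pairs in each comparison, 0, 0 and 1 had a correlation of deviations over 0.1, and 1, 0 and 0 mice correlated best with their own number. With the replicate number as a block, 0 genes were called in exercise against control, and 0 and 9 immediate early genes passed in CSDS against control and exercise against control; the numbers of lists called and of genes in the other comparisons stayed within 1.5 times.

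Leaving out 1 library at a time gave 0 to 625 genes in exercise against CSDS (625 without exercise replicate 4, 43 without CSDS replicate 5) and 0 to 13 in exercise against control (13 without exercise replicate 4), and 0 in every case in CSDS against control, where DESeq2 called 1 and 401 to 956 genes had an unadjusted p under 0.05. Immediate early genes numbered 0 to 4 (0 without control replicates 2 or 3 or CSDS replicates 1, 4 or 6), 0 to 3 (3 without exercise replicate 4) and 8 to 17 (8 without control replicate 2). In exercise against control 8 to 18 lists were called, and the correlation ran from -0.60 (without CSDS replicate 4) to -0.39 (without control replicate 3).

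Of the log2 fold changes of the genes named in the text, 2441 kept direction and side of the threshold over the alternatives, 114 came to pass, 56 no longer passed and 41 turned sign. All 41 belong to fixed genes, none of which passed over all genes with edgeR on all libraries. Dcx in CSDS against control was -0.0034 without a filter, -0.0049 with only the groups compared and -0.059 with voom, and -0.056 to 0.076 over left-out libraries. Nr3c1 in exercise against control was -0.00089 without a filter, -0.026 with 1 surrogate variable and -0.033 to 0.22 over left-out libraries. Npas4 in CSDS against control was 0.23 with voom, -0.40 to 0.15 over left-out libraries, and without control replicate 2 it was 0.095 with 1 surrogate variable, 0.088 with the covariates, 0.15 with DESeq2 and 0.11 after GC correction. Fkbp5 and Gfap in exercise against CSDS were 0.053 and 0.13 with 1 surrogate variable, and Gfap 0.036 without control replicate 2 as well. Gfap in exercise against control was -0.030 to 0.28 over left-out libraries and -0.037 with DESeq2 without control replicate 2. Ttr was -0.97 to 0.018 in CSDS against control and -1.02 to 0.35 in exercise against CSDS over left-out libraries. With the covariates and without control replicate 2, Nr3c1 was 0.0029, Bdnf -0.029, Gfap -0.053 and Mbp 0.014 in CSDS against control, and Fkbp5 -0.086 and Gfap -0.14 in exercise against control. After GC correction Bdnf in exercise against CSDS was -0.10, -0.10 without control replicate 2 and -0.20 without exercise replicate 4, and in exercise against control -0.066 and -0.055 with those libraries left out. Depth was not varied. At 18911080 to 24136591 counts per library and 6 mice per group, at most 38.0% of genes with a simulated 1.5-fold change were recovered.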

Other observations

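All observations in this part were made after the data were seen. Several lists were called in no comparison. Microglia markers had medians of 0.02, -0.02 and -0.05 in CSDS against control, exercise against CSDS and exercise against control over 24 members. Astrocyte markers had 0.01, -0.01 and -0.04 over 24 members, and myelinating oligodendrocyte genes -0.03, -0.01 and -0.06 over 30 members, and camera called none of them in any comparison. Genes of corticosteroid and CRH signalling had medians of -0.05, -0.06 and -0.02 over 10 members, cytokines and NF-kB inflammatory genes -0.01, -0.06 and -0.14 over 19 members. Complement genes had 0.02, -0.08 and -0.09 over 16 members, and presynaptic vesicle genes 0.02, -0.04 and -0.05 over 36 members, again without a call. A missing call does not show that levels were equal.

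Circadian clock genes had a negative log2 fold change in 18 of 19 members in CSDS against control (median -0.16, camera adjusted p = 0.000117, adjusted p = 0.606 with an estimated correlation) and in 15 of 19 in exercise against control (median -0.18, camera adjusted p = 0.0262, adjusted p = 0.904 with an estimated correlation), with no member passing over the list alone. Control replicate 2 had a level of 1.59 for this list (-0.16 to 0.25 in the other controls). Without it the circadian list had an adjusted p of 0.0253 and 0.478 in these comparisons, and with GC correction as well the median in CSDS against control was -0.09, against -0.18 with GC correction alone. Apoptosis and p53 genes had a median of -0.11 over 21 members in CSDS against control (camera adjusted p = 0.0116, adjusted p = 0.606 with an estimated correlation). The exact permutation p of their level per mouse was 0.00866, or 0.298 after adjustment over the 55 lists. CA1 pyramidal cell markers had a median of 0.27 in the same comparison, with 17 of 20 members on the higher side (camera adjusted p = 0.00082, adjusted p = 0.606 with an estimated correlation). Control replicate 2 was at 4.79 log2 CPM for the CA1 markers against 5.72 to 6.51 in the other 17 libraries, with 13 of the 20 lowest there, and without it the adjusted p was 0.0336. Glutamate receptor and postsynaptic density genes had a median of 0.14 with 33 of 45 members on the higher side (camera adjusted p = 0.000156, adjusted p = 0.606 with an estimated correlation).

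Of the gene identifiers without a symbol, the one with the most counts had a mean share of 0.239% ± 0.0646 of all counts in control, 0.327% ± 0.210 in CSDS and 0.429% ± 0.0868 in trained mice (SD, n = 6). The exact permutation p of trained against control mice was 0.00216, the smallest these groups allow, and what the identifier stands for was not analysed here.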
